A study of Homo sapiens with 6 samples.

How the data were processed

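Gene expression was measured by RNA sequencing in Caki-1 cells, an established human renal carcinoma cell line, 60 h after transfection with siRNA against HOTAIRM1 (3 libraries) or with control siRNA (3 libraries). Per the labels' protocols, total RNA was purified with spin columns and the libraries were made with a kit that keeps strand information. The submitters' processing notes name kallisto, sleuth, HISAT2, edgeR and the genome build hg38, with no versions, roles or order. Whether strand was used in quantification, and which annotation was used, is not given in the sources used here.

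The main table gives 1 value per gene and library for 62739 genes on the TPM scale, which corrects for transcript length and library total. The authors deposited these values without read counts. The library totals ranged from 972264 to 1032410, so the values are not plain TPM, and they were treated as a signal on the TPM scale that the authors had scaled further between libraries. In such a table a gene's value depends on an estimated transcript length and on the values of all other genes, and very short RNAs can receive large values from few reads. Transfer RNAs of the mitochondrial genome took 28.5% to 30.6% of each library's total, and protein-coding genes took 63.1% to 65.3%. TPM keeps no depth, so the depth of the libraries is unknown and no counting interval could be given.

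A second table, the authors' gene-level comparison, lists 31532 gene symbols. Per the file headers, it gives a log2 fold change P minus N, an average log2 CPM, a likelihood ratio score, a p-value and a false discovery rate, and the submitters' processing notes name edgeR. P and N are the letters that the labels use for the HOTAIRM1 siRNA and control siRNA libraries. The counting, the filter and the model behind it are not given in the sources used here. In this authors' deposited table, 8412 symbols had values and 23120 had none. Another table, per the file headers from sleuth, lists 40 genes with a p-value, a q-value, an effect b and its standard error, by the authors. No new test was run on the authors' deposited tables, which were only described.

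Differences were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend in the prior, on the 15409 genes with a mean of at least 1 over the 6 libraries. Tests were two-sided, adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The design had been written for plain TPM, and the same test was kept for the scaled values. The fit estimated 2.41 prior degrees of freedom and a median residual SD of 0.0888 on the log2 scale. Tested on simulated data with the means and spreads of all 15409 genes and 200 changed genes, the limma step for HOTAIRM1 siRNA against control siRNA recovered 74.6% of the changes of 0.5, 94.0% of those of 1 and 98.5% of those of 2 on the log2 scale, with 7 false calls among 185. The 200 changed genes were drawn only from genes with values of about 5 or more, so recovery at lower values was not tested. These simulated values had normal errors around the fitted means, independent between genes, which real libraries need not have. The adjustment is also less strict when 200 genes truly change than when few do, so these rates are not the power of the real comparison. In the real fit DDAH1, with a log2 difference of -0.66, did not pass (limma adjusted p = 0.0854).

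Gene lists were tested with camera (limma), with a preset correlation of 0.01 between genes, over the 35 of 37 fixed lists that had at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. Trends over transcript length or GC content were removed per library with a natural spline of 5 degrees of freedom before a repeat of camera, on the genes with an annotated value. Gene identifiers were matched to symbols, positions and gene types of the GENCODE v29 annotation of hg38; 56847 of the 62739 identifiers matched. The others include copies on alternate sequences, which share reads with the genes they copy. For HOTAIRM1 an exact permutation test over the 6 libraries was added, which with 3 against 3 cannot go below a two-sided p of 0.1. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the description of the authors' deposited tables and the plots. Intervals of shares are exact Clopper-Pearson 95% intervals, which treat genes as independent although they come from the same libraries.

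The tests, the gene lists, the alternatives listed here and the rule for named genes were fixed before the data were examined. The rule took HOTAIRM1 and the tested genes of the HOXA cluster. It also took, in each direction, the 8 genes with the largest change among those past the threshold, with a mean of at least 5 in either group, no overlap between groups and a symbol that is not a clone name, filled up by the smallest p and then said not to have passed. It took the 4 hypoxia list members and the 3 members of each called list with the smallest p, and the 3 smallest q values of the authors' deposited sleuth table. Genes named outside this rule, as the few members of a count or as calls of the authors' deposited tables, were chosen after their values were seen. Some genes that the rule takes are not reported here. The alternatives fixed in advance were pseudocounts of 0.1 and 0.5, median-of-ratios and quantile scaling, the replicate number as a block, a robust prior, array weights, no filter, a minimum of 5, protein-coding genes only rescaled to a common total, and leaving out each library. A test of single transcripts was planned but not run, because the table is per gene, and tests on counts were not run, because the files hold no counts. Nothing states that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.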

Results

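The transcriptome of Caki-1 cells was compared between libraries labelled HOTAIRM1 siRNA (n = 3) and libraries labelled control siRNA (n = 3), all taken 60 h after transfection, to ask which RNAs change when HOTAIRM1 is targeted. HOTAIRM1 is a long non-coding RNA transcribed from the HOXA gene cluster, and siRNAs are short RNAs that direct the cleavage of a matching transcript. Values are on the TPM scale. Between 15227 and 15384 genes per library had a value of 1 or more, and the libraries' log2 values correlated across tested genes with Pearson's r between 0.971 and 0.978.

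HOTAIRM1 itself was not lower in the libraries labelled HOTAIRM1 siRNA. Its level was 21.04 ± 2.08 there (SD, n = 3) and 18.8 ± 0.249 in the libraries labelled control siRNA (SD, n = 3). The single values were 20.6, 23.3 and 19.2 in the libraries labelled HOTAIRM1 siRNA and 19.0, 18.6 and 18.6 in the libraries labelled control siRNA, so the groups did not overlap, in the direction opposite to a knockdown. The log2 difference was 0.15 (SE 0.071, 95% interval −0.017 to 0.32), with a limma adjusted p of 0.610 and an exact permutation p of 0.1, the smallest that 3 against 3 allows. As a fold this was 1.11 (95% interval 0.988 to 1.25), so that under the labels as given the interval leaves out any level below 0.988 of the control. If the groups were exchanged, HOTAIRM1 would be 10.8% lower in the targeted libraries. HOTAIRM1 (ENSG00000233429) lies on chromosome 7 from 27095647 to 27100265 in hg38 with 6 annotated transcripts and is annotated as an antisense RNA, so its value can include reads of the other strand unless strand was used. The authors' deposited gene-level table lists HOTAIRM1 without values.

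The deposited tables did not share one direction. In the authors' deposited gene-level table, 122 symbols had a false discovery rate below 0.05, of which 81 had a positive and 41 a negative log2 fold change P minus N. Of these, 110 could be matched to a tested gene, and 105 of the 110 (95.5%, 95% interval 89.7% to 98.5%) had the opposite sign in the difference between the libraries labelled HOTAIRM1 siRNA and control siRNA. Over the 6688 genes with values in both, the 2 sets of differences had a Pearson's r of -0.485 and a Spearman's rho of -0.624 across genes, which are not independent replicates. In the authors' deposited sleuth table of 40 genes, 38 passed the expression filter here and 38 of the 38 had the opposite sign. The authors' 2 tables shared 14 called genes, and 14 of the 14 had the same sign in both. The files do not tell which table has its groups reversed. The directions below are therefore those of the libraries as labelled, and each would turn if the labels of the value table are the ones exchanged.

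**Figure D1:**
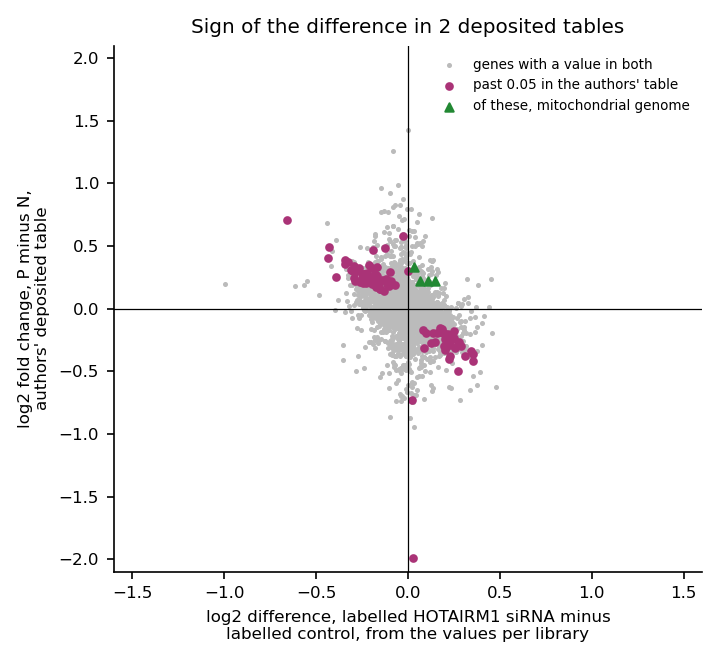
Each grey point is 1 of 6688 genes, with the log2 difference between the libraries labelled HOTAIRM1 siRNA and control siRNA on the x axis and the log2 fold change P minus N of the authors' deposited table on the y axis. Coloured points have a false discovery rate below 0.05 in that table: 105 of 110 lie in the quadrants of opposite sign, and 4 of the other 5 are genes of the mitochondrial genome.

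Only 2 of the 15409 genes tested passed the threshold, and both were small RNAs. MIR6851, a microRNA gene of 67 bases on chromosome 9 (33467869 to 33467935), was listed at 0 in each library labelled HOTAIRM1 siRNA and at 17.9, 21.9 and 23.0 in those labelled control siRNA (limma adjusted p = 4.69e-05). ENSG00000278421, an RNA of 71 bases on chromosome X (74274341 to 74274411), was listed at 0 in the former and at 10.9, 12.9 and 22.2 in the latter (limma adjusted p = 0.0122). An RNA this short can be listed at 0 through a failed estimate, and neither gene is in the authors' deposited sleuth table or has a value in their gene-level table. An unadjusted p below 0.05 was reached by 1329 genes (8.62%), 596 of them higher and 733 lower in the libraries labelled HOTAIRM1 siRNA. The groups did not overlap for 2407 genes (15.6%), against 10% by chance. Without control siRNA replicate 1 the count of calls was 6, without control siRNA replicate 2 it was 4, and without HOTAIRM1 siRNA replicate 1 it was 4. With protein-coding genes only, where the 2 small RNAs were not tested, 2 other genes passed after rescaling to a common total, and 4 passed without rescaling, a fit added after seeing the data.

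Among longer genes, the lowest p belonged to genes with less RNA in the libraries labelled HOTAIRM1 siRNA, none of which passed over all genes with equal weights and the standard prior. DDAH1, an enzyme that degrades the nitric oxide synthase inhibitor asymmetric dimethylarginine, was at 9.79 ± 0.516 in the libraries labelled HOTAIRM1 siRNA and 16.01 ± 0.822 in those labelled control siRNA (SD, n = 3 each), a log2 difference of -0.66 (SE 0.057, limma adjusted p = 0.0854). ANGPTL4, a secreted inhibitor of lipoprotein lipase, was at 6.39 ± 0.621 and 11.1 ± 0.527, a log2 difference of -0.71 (SE 0.073, limma adjusted p = 0.119). These are the 2 genes that passed when only protein-coding genes, rescaled to a common total, were tested (limma adjusted p = 0.0174 for DDAH1 and for ANGPTL4). Without rescaling, FJX1 and SERF1A passed as well (limma adjusted p = 0.0271 and 0.0385). Over genes of every type, DDAH1 passed with a robust prior (limma adjusted p = 0.0436), DDAH1, FJX1 and ANGPTL4 passed with array weights (0.0440 each), and DDAH1 and FJX1 passed with a minimum of 5 (0.0305 and 0.0442). FJX1, a secreted protein of the four-jointed family, was at 14.8 ± 0.534 and 20.6 ± 0.526, a log2 difference of -0.45 (limma adjusted p = 0.119). The list continued with MPRIP, which binds the myosin phosphatase, at 41.8 and 52.1, TAP2, a peptide transporter of antigen presentation, at 9.62 and 13.0, and CDC25A, a phosphatase that drives entry into S phase, at 8.33 and 10.6. A Y RNA copy on chromosome 9 was at 1.56 and 5.37, and its value is uncertain because Y RNAs have many near-identical copies. MPRIP, TAP2, CDC25A and the Y RNA copy had limma adjusted p values of 0.181, 0.225, 0.225 and 0.163. The authors' deposited gene-level table gives log2 fold changes of -0.015 for MPRIP, -0.0094 for TAP2 and 0.31 for CDC25A. Their false discovery rates were 0.9925, 0.969 and 2.55e-05. Their mean log2 CPM in that table was 0.27, 6.80 and 6.09, although MPRIP had the highest level of the 3 in the libraries here. The MPRIP fold change there may therefore not be that of the gene, and it is no evidence against the difference seen here. The authors' deposited sleuth table lists MPRIP with b = 0.33 and CDC25A with b = 0.36, and does not list TAP2.

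DDAH1, ANGPTL4 and FJX1 were also the 3 genes with the smallest q values in the authors' deposited sleuth table. Its q values were 6.85e-26 for DDAH1, 3.73e-15 for ANGPTL4 and 2.65e-08 for FJX1. Its effects b were 0.72 (SE 0.063) for DDAH1, 0.81 (SE 0.091) for ANGPTL4 and 0.49 (SE 0.070) for FJX1, with the sign opposite to the libraries as labelled. In the authors' deposited gene-level table DDAH1 had a log2 fold change of 0.71 (false discovery rate 4.48e-30), and ANGPTL4 and FJX1 had no value. All 38 tested genes of the sleuth table had an unadjusted p below 0.05 here, the highest being 0.00577. The sleuth table compares the same 2 groups of libraries, so this overlap of genes is no independent support for them.

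The genes with more RNA in the libraries labelled HOTAIRM1 siRNA and the lowest p did not pass over all genes either. ALDH3B1, an aldehyde dehydrogenase, was at 23.7 ± 0.195 in the libraries labelled HOTAIRM1 siRNA and 18.5 ± 0.631 in those labelled control siRNA (SD, n = 3 each), a log2 difference of 0.34 (SE 0.040, limma adjusted p = 0.163). SDC4, a cell surface heparan sulphate proteoglycan, was at 122 ± 2.22 and 100.3 ± 3.52, a log2 difference of 0.28 (limma adjusted p = 0.267), and the authors' deposited gene-level table gives -0.27 for it with a false discovery rate of 8.19e-07. SLC30A5, a zinc transporter, was at 82.0 ± 7.85 and 59.9 ± 2.63 (limma adjusted p = 0.413). ADAMTS3, a procollagen peptidase, was at 14.8 and 12.4, CDH6, a cadherin of the renal tubule, at 16.2 and 13.6, and LMO7, a protein of adherens junctions, at 15.1 and 11.9, each with a limma adjusted p of 0.413. NARF-AS2, an antisense RNA, was at 6.99 and 4.59 (limma adjusted p = 0.267). SERF1A was at 8.86 and 5.82 (limma adjusted p = 0.163), but it has a near-identical copy, SERF1B, and the sum of both copies overlapped between the groups, with a log2 difference of -0.17.

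**Figure D2:**
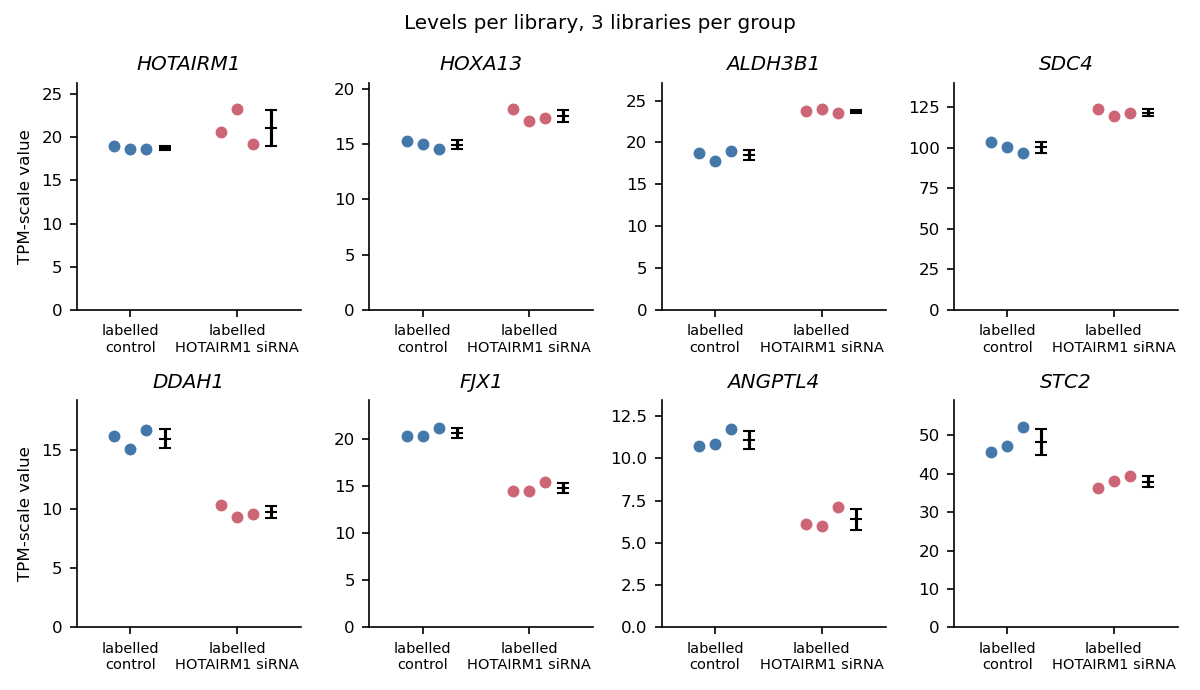
Points are the TPM-scale values of 8 genes in each library (y axes start at 0), with libraries labelled control siRNA on the left and libraries labelled HOTAIRM1 siRNA on the right of each panel, and bars show mean ± SD (n = 3). HOTAIRM1 lay between 18.6 and 19.0 in the former and between 19.2 and 23.3 in the latter, and DDAH1 between 15.1 and 16.7 in the former and between 9.38 and 10.4 in the latter.

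The genes of the HOXA cluster, in which HOTAIRM1 lies, did not pass the threshold, and 12 of the 15 tested had a higher mean in the libraries labelled HOTAIRM1 siRNA. HOXA13, the gene at the far end of the cluster from HOTAIRM1, was at 17.6 ± 0.558 against 14.96 ± 0.385 (SD, n = 3 each), a log2 difference of 0.22 (SE 0.043, limma adjusted p = 0.487). HOXA10-AS, an antisense RNA, was at 3.72 ± 0.396 against 2.59 ± 0.221, a log2 difference of 0.39 (SE 0.090, limma adjusted p = 0.4999). Adjusted over the list alone, 2 genes passed, and over all genes tested 0 passed. HOXA2 was at 2.23 and 1.97, HOXA3 at 16.9 and 16.3, and SKAP2 at 23.2 and 24.1. HOXA10 was the most abundant member, at 59.0 and 57.7, followed by HOXA9 at 28.1 and 27.6. HOXA4, HOXA5, HOXA7 and HOXA11 had log2 differences of -0.05, 0.13, 0.03 and -0.04. The antisense RNAs HOXA-AS2, HOXA11-AS and HOTTIP had log2 differences of 0.09, 0.08 and 0.06. As a list the cluster had a mean log2 difference of 0.07 and missed the threshold with camera (adjusted p = 0.0701; adjusted p = 0.810 with an estimated correlation), while fry, which asks only whether the list's genes move one way, gave an adjusted p of 0.0371. The authors' deposited gene-level table calls 1 gene of this list, HOXA13, with a log2 fold change of -0.21 (false discovery rate 0.00827).

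Hypoxia-inducible genes, which are a central programme of renal carcinoma through the VHL and HIF pathway, did not pass as a group moving one way, but passed a test for change in either direction. Of the 50 tested members, 23 had a higher and 27 a lower mean in the libraries labelled HOTAIRM1 siRNA, with a mean log2 difference of -0.03 (camera adjusted p = 0.393; adjusted p = 0.810 with an estimated correlation). None passed over all genes with limma, 3 passed adjusted over the list alone, and 11 (22%) had an unadjusted p below 0.05, against 8.62% of all genes tested. With fry the adjusted p was 0.523 for a change one way and 8.10e-06 for change in either direction, the lowest of the 35 lists. That second test does not compare a list with other genes, and 16 of the 35 lists passed it. The 4 members with the lowest p were ANGPTL4, STC2, SLC2A3 and JMJD6, each lower in the libraries labelled HOTAIRM1 siRNA. STC2, a secreted glycoprotein, was at 37.9 ± 1.45 and 48.3 ± 3.36 (log2 difference -0.34, limma adjusted p = 0.413). SLC2A3, a glucose transporter, was at 5.22 ± 0.214 and 6.64 ± 0.335 (log2 difference -0.30, limma adjusted p = 0.487). JMJD6, a hydroxylase, was at 53.7 ± 1.68 and 59.0 ± 0.827 (log2 difference -0.13, limma adjusted p = 0.4999). The authors' deposited gene-level table calls 2 members of this list, STC2 with 0.36 and SLC2A3 with 0.34 on the log2 scale, and their deposited sleuth table lists ANGPTL4 and STC2. The 21 tested components of the HIF pathway itself had a mean log2 difference of -0.01 (camera adjusted p = 0.803).

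Of the 35 gene lists tested, 5 passed with camera at the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.810; at an unadjusted camera p below 0.05 there were 8. In none of the 5 called lists did a gene pass with limma, either over all genes or adjusted over the list alone. Cytosolic ribosomal proteins were lower in the libraries labelled HOTAIRM1 siRNA for 73 of 75 genes, with a mean log2 difference of -0.10 (camera adjusted p = 1.94e-07; adjusted p = 0.810 with an estimated correlation). The members with the lowest p were RPL14 at 825 ± 67.4 and 1048 ± 119, RPS29 at 218 ± 10.5 and 252 ± 18.3, and RPS21 at 482 ± 45.3 and 576 ± 66.4 (SD, n = 3 each), all of which have processed copies in the genome that share reads. Nuclear genes of oxidative phosphorylation were lower for 43 of 49, with a mean of -0.08 (camera adjusted p = 9.32e-04; adjusted p = 0.810 with an estimated correlation). Their lowest p values were those of NDUFC2 at 160 ± 3.12 and 204 ± 26.3, NDUFA1 at 97.0 ± 4.57 and 112 ± 9.60, and CYC1 at 121 ± 1.78 and 129 ± 4.36.

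Genes of the mitochondrial genome were higher in the libraries labelled HOTAIRM1 siRNA for 15 of 15, with a mean log2 difference of 0.12 (camera adjusted p = 9.32e-04; adjusted p = 0.810 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase, was at 10930 ± 114 and 9565 ± 820, MT-ND4L, a subunit of complex I, at 5790 ± 327 and 4513 ± 970, and MT-CYB, cytochrome b, at 3543 ± 169 and 3142 ± 330 (SD, n = 3 each). The authors' deposited gene-level table calls 4 members of this list, MT-ND4, MT-ND5, MT-ND6 and MT-CO3, with log2 fold changes of 0.22, 0.22, 0.33 and 0.22. These 4 keep their sign between the tables, unlike most called genes. In the libraries as labelled their log2 differences were only 0.15, 0.07, 0.04 and 0.11, and none passed the threshold with limma. MT-CO1, MT-CYB and MT-ND4L, not called in that table, also had positive log2 fold changes there, of 0.17, 0.17 and 0.19. The signs of the remaining members there are not reported here. An exchange of groups or of sign alone would have given these genes opposite signs, so it does not account for them. Their differences here are small against the spread between libraries, so the shared sign alone does not establish them as an exception.

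Targets of MYC were lower for 26 of 30, with a mean log2 difference of -0.06 (camera adjusted p = 0.00790; adjusted p = 0.810 with an estimated correlation). BOP1, NIP7 and RRP9, factors of ribosome assembly, were at 48.3 and 55.6, 67.3 and 75.0, and 22.2 and 24.9. Genes of the S phase were lower for 26 of 39, with a mean of -0.04 (camera adjusted p = 0.0427; adjusted p = 0.810 with an estimated correlation), and after removing each library's trend over transcript length the mean was -0.04 and the list missed the threshold (camera adjusted p = 0.0526). MCM5, of the replicative helicase, was at 26.0 and 30.1, and RFC4, of the clamp loader, at 43.9 and 49.5. Genes of the G2 and M phases did not pass (mean -0.01, camera adjusted p = 0.622).

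Control siRNA replicate 1 stood apart in several of these lists. In it the ribosomal protein list lay 0.19 above its mean over the 6 libraries on the log2 scale, the nuclear oxidative phosphorylation list 0.16 above, the MYC target list 0.08 above, the S phase list 0.03 above and the mitochondrial genome list at -0.17. Without that library 0 lists passed with camera. The mean log2 difference went from -0.10 to -0.04 for ribosomal proteins (camera adjusted p = 0.129), from -0.08 to -0.01 for nuclear oxidative phosphorylation (0.606), from 0.12 to 0.06 for the mitochondrial genome (0.0911) and from -0.06 to -0.04 for MYC targets (0.129). For the S phase it was -0.042 with that library and -0.035 without it (0.129), so that list's difference rested little on it. With all 6 libraries, the list means of the groups overlapped for ribosomal proteins and nuclear oxidative phosphorylation and did not overlap for the mitochondrial genome, MYC targets and the S phase, each of the latter with an exact permutation p of 0.1, the smallest possible. The gap was narrow for the mitochondrial genome (control siRNA replicate 2 at 0.0289, HOTAIRM1 siRNA replicate 2 at 0.0305). It was also narrow for MYC targets (control siRNA replicate 3 at -0.00596, HOTAIRM1 siRNA replicate 3 at -0.00775). The heat shock and HOXA cluster lists, which camera did not call, did not overlap either.

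**Figure D3:**
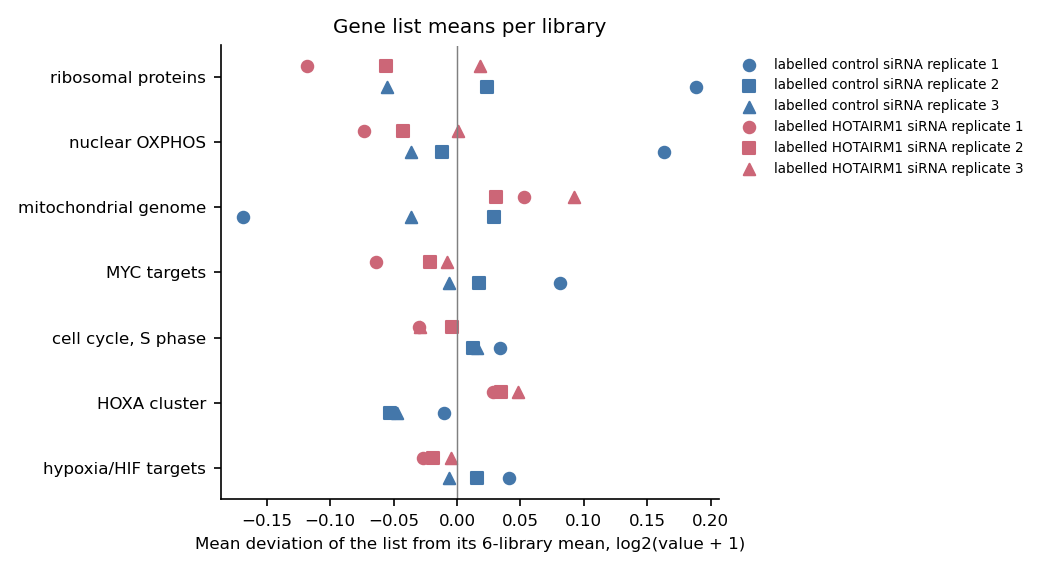
Each point is 1 library's mean deviation, on the log2(value + 1) scale of the x axis, of a gene list from that list's mean over the 6 libraries, for the 5 called lists, the HOXA cluster and the hypoxia list (rows). Control siRNA replicate 1 lies apart at 0.19 for ribosomal proteins and at -0.17 for the mitochondrial genome, and the libraries labelled HOTAIRM1 siRNA (-0.12, -0.06 and 0.02 for ribosomal proteins) overlap the other 2 control libraries (0.02 and -0.06).

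The other lists did not pass. Of the 30 lists that camera did not call, the adjusted p ranged from 0.0701 to 0.873. Glycolysis genes had a mean log2 difference of -0.05 (camera adjusted p = 0.259), targets of p53 -0.02 (0.706), the interferon response -0.0034 (0.393), the unfolded protein response -0.02 (0.665), the integrated stress response -0.01 (0.393), genes of the epithelial-mesenchymal transition -0.01 (0.829), chromatin genes of the polycomb complex 0.03 (0.417) and genes of the other HOX clusters 0.01 (0.706). Among markers of other cell types, 0 of 18 leukocyte markers and 1 of 13 endothelial markers, EGFL7 at 10.2, had a mean of at least 1. Of 13 fibroblast markers 7 had a mean of at least 1 over the 6 libraries, led by the matrix genes FBN1 at 65.3 and COL5A2 at 58.0, and the list had a mean log2 difference of 0.0017 (camera adjusted p = 0.840).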

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

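Settings added after seeing the data were the rescaling to a common total, the removal of mitochondrial transfer RNAs, a minimum of 10, 3 further fits of protein-coding genes, fry for either direction, and every alternative for the count of called lists. The log2 difference of HOTAIRM1 stayed above 0 and short of the threshold in all 18 alternatives run for it (0.08 to 0.23, limma adjusted p 0.266 to 0.872), and the hypoxia list stayed short of it in 24 alternatives (camera or one-direction fry adjusted p 0.216 to 0.969) and passed in 1, fry for change in either direction (8.096e-06), which asks a different question. The main fit called 2 genes, 0 higher and 2 lower. The count was 5 with array weights, 1 without a filter, 4 with a minimum of 5 and 1 with a minimum of 10. For protein-coding genes it was 8 with a robust prior (3 higher, 5 lower), 10 with a minimum of 5 (4 higher, 6 lower) and 4 without rescaling (1 higher, 3 lower). Without mitochondrial transfer RNAs it was 4 (2 higher, 2 lower). Leaving out 1 library gave 3 to 6 genes. Fewer or more genes enter the adjustment under the filters, and the cause of the other differences was not tested. The replicate numbers did not pair the libraries: same-numbered libraries had correlations of 0.022, 0.038 and -0.058 in their deviations from the group means, 2 of the 6 libraries correlated best with their own number, and the replicate block gave 1 gene. The count of called lists was 5 in the main fit, 0 with quantile normalization, 1 with array weights, 8 without a filter, 3 with a minimum of 10, 0 with an estimated correlation, 1 with fry in one direction, the HOXA cluster, and 16 with fry in either direction. Leaving out 1 library gave 0 to 5 lists, 0 without control siRNA replicate 1 and 3 without HOTAIRM1 siRNA replicate 1. DDAH1 passed with a robust prior, array weights, a minimum of 5 and each of the 4 protein-coding fits (limma adjusted p over its 22 alternatives 0.00701 to 0.380), and ANGPTL4 with array weights and the 4 protein-coding fits (0.00701 to 0.571). FJX1 passed with array weights, a minimum of 5 and the 3 added protein-coding fits (0.0260 to 0.542), SERF1A with those 3 fits, SDC4 and SLC30A5 with 2 of them, and ALDH3B1 and MPRIP with 1. MIR6851 passed in all 18 alternatives in which it was tested (limma adjusted p 3.78e-06 to 0.00747). The planned tests of single transcripts and of counts were not run.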

Other observations

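The tests of the direction of the tables and of the spread between single libraries were chosen after the result was seen. Some genes that the authors' deposited tables call lie outside the rule for named genes and were chosen after their values were seen. The list of extracellular matrix and mesenchymal genes held FN1 (fibronectin) at -0.17 and TNC (tenascin C) at 0.20 in the authors' deposited gene-level table, with false discovery rates of 0.000984 and 0.0324. FN1 was at 3020 ± 59.6 in the libraries labelled HOTAIRM1 siRNA and 2862 ± 191 in those labelled control siRNA (SD, n = 3 each), and TNC at 12.1 ± 4.95 and 15.01 ± 8.32. COL4A1, a chain of basement membrane collagen, was given at 0.14 in that table, and it was at 167 ± 4.51 and 183 ± 4.25. The authors' deposited sleuth table lists CDKN1C, an inhibitor of cyclin-dependent kinases, with b = 0.47, CCND1, cyclin D1, with b = 0.22, and CDC25A with b = 0.36, all 3 with the opposite sign in the libraries as labelled. It also lists THBS1 (thrombospondin 1) with b = -0.23 and TNFRSF11B (osteoprotegerin) with b = -0.31.

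Genes of the proximal tubule, the segment from which clear cell renal carcinoma is held to arise, included 3 of 10 tested members that passed adjusted over the list alone, and 0 over all genes tested. CDH6 and GPX3, a secreted glutathione peroxidase, had log2 differences of 0.23 and 0.45, and ANPEP, a brush border peptidase, had -0.18. As a list they did not pass with camera (adjusted p = 0.219; adjusted p = 0.810 with an estimated correlation).

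A first pattern is the opposite sign of the authors' deposited tables and the values per library. Unrelated tables would put the share of opposite signs near an even split, and the share was 95.5%, far from that. This share is the observation that raised the question, so it is no separate test. Its 95% interval treats genes of the same 6 libraries as independent. Either the group names of the value table or the sign of both comparison tables may be exchanged, and the level of HOTAIRM1 was the test. Neither exchange by itself would leave the mitochondrial genome genes named above with the same sign in the value table and the gene-level table. The 95% interval of its difference ran from −0.01672 to 0.3237 and included 0, so it excluded neither exchange. The test also presumes that the siRNA lowered HOTAIRM1 RNA. That was not seen under the labels as given (fold 1.11, 95% interval 0.988 to 1.25). With the groups exchanged HOTAIRM1 would be only 10.8% lower. With 3 libraries per group and no clear knockdown under either labelling, the level of HOTAIRM1 cannot tell the 2 exchanges apart. No biological explanation was tested, since a sign does not depend on the cells.

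A second pattern is the lower ribosomal protein list in the libraries labelled HOTAIRM1 siRNA. Removing each library's trend over transcript length moved the mean log2 difference from -0.104 to -0.084. Removing its trend over GC content left it at -0.104, so most of the difference remained. At the preset correlation the camera p was 3.959e-07 and 1.135e-09. With an estimated correlation the list was not called before or after either removal (camera adjusted p = 0.810, 0.819 and 0.741). These p values therefore cannot decide on either trend. Length was the mean over a gene's annotated transcripts, so a trend over the lengths of the RNAs present was not tested. The list means of the libraries overlapped between the groups (exact permutation p = 0.2), and without control siRNA replicate 1 the mean log2 difference went from -0.10 to -0.04 and the list was no longer called, which is consistent with a spread between single libraries in genes that move together (estimated correlation 0.858). An effect of the siRNA of this size stays open as a biological explanation, because 3 libraries per group cannot separate it from that spread.

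The last pattern is that many abundant genes have no value in the authors' deposited gene-level table: of 7076 genes with a mean of at least 10 that it lists, 4255 (60.1%) have one. If reads shared by several transcripts had gone uncounted, genes with 1 annotated transcript would have a value more often. Among protein-coding genes the share was 63.5% with 1 transcript and 60.6% with 5 or more, a difference of 2.89 points. The share was 61.1% for genes that overlap a gene on the other strand and 58.8% for the others, and the latter minus the former was -2.28 points, so both explanations lack the gap of 20 points set for them. In that same table, symbols that share their values with another number 747 and fall into 369 groups with identical values, and in 369 of the 369 one symbol begins with the other, as MAF and MAFG. Of 2193 genes with a mean of at least 30 here and a value there, 404 had a mean log2 CPM under 2 in that table. Some of its fold changes may therefore not belong to the symbol shown, which also limits the correlations with it. A join of tables by partly matched names may have produced the shared values, which was not tested, and no biological explanation was tested.

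The 6 libraries can be split in 10 ways into groups of 3, too few for a share below 0.05. The real split called 2 genes and the highest other split 4, and 9 of the 10 splits called at least 2. It called 5 lists and the highest other split 7, with 2 of the 10 splits at 5 or more.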
